A study of Danio rerio with 15 samples.

How the data were processed

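Poly(A) RNA of dechorionated whole zebrafish embryos was sequenced in 15 libraries, 1 for each genotype, stage and control set named in the labels. The genotypes were wildtype, the line labelled MZnup133 (depletion of nup133, with MZ read as maternal-zygotic), the line labelled Tgnup133 (transgenic overexpression of nup133) and the line labelled Melys (depletion of elys, the gene that zebrafish nomenclature calls ahctf1). The stages were 3, 4 and 4.5 hours post fertilization (hpf). Each stage had 1 wildtype library named as the control for Tgnup133 and MZnup133 and another named as the control for Melys, called here the nup133 set and the elys set. The wildtype columns of the value table do not carry the control set, so each was assigned by the leading number it shares with the mutant columns of its set.

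The deposited values were FPKM, fragments per kilobase of transcript scaled to the mapped fragments of the library, computed by the authors for each gene and library. Per the submitters' processing notes, Trim Galore, STAR 2.5.3a, Cufflinks 2.2.1 and the genome build GRCz11 were used. Their order, options and annotation version are not given in the sources used here. The table held 23800 lines, of which 74 repeated another line and were dropped, which left 23726 genes. Of these, 71 carried no symbol, and 64 of the 71 were found in the reference gene table. Symbols were otherwise used as the file pairs them with gene identifiers, and 363 symbols were shared by more than 1 identifier. The file gives no coordinates, and none are printed. Read counts were not analysed here, so the depth of each library is unknown and no counting interval or floor is given. The sum of FPKM ranged from 508714.6 to 575118.3 per library, and 12356 to 13057 genes per library had at least 1 FPKM. An FPKM of exactly 0 can be an absent transcript or an estimate that failed. Reads shared between near-identical gene copies or overlapping genes could have been split by the upstream estimation, so single genes that are present in one line and at 0 in another are uncertain.

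The tests below were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, for the 13493 genes with a mean of at least 1 FPKM over the 15 libraries. All tests were two-sided, with a variance trend and Benjamini-Hochberg adjustment over the genes tested, and the threshold was an adjusted p of 0.05. The per-stage comparisons came from 1 fit with 12 genotype-by-stage means and a control set term. That fit had 2 residual degrees of freedom from the pairs of wildtype libraries and 2.36 prior ones, so each lone mutant or transgenic library was assumed to vary like the wildtype libraries. The comparisons over 3 stages came from a fit with a level for each control set and stage and 1 effect per mutant or transgenic genotype, with 6 residual and 3.52 prior degrees of freedom. There, differences between stages in the genotype effect enter the residual spread. The wildtype series of both sets were compared in another fit of all 15 libraries, with a level per stage and a term per series and 8 residual degrees of freedom. The p-values measure the spread between these libraries only, since nothing in the labels says which libraries came from separate clutches.

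For gene groups, 19 lists were fixed before the data were examined. They covered early zygotic genes, maternal oocyte genes, maternal transcription regulators of genome activation, nuclear pore components, nuclear transport factors, damage response genes, heat shock and immediate early genes, cell cycle, dorsal organizer, ventral and BMP genes, mesoderm and endoderm, enveloping layer and epidermis, yolk syncytial layer, neuroectoderm, germ plasm and primordial germ cells, adult tissue and blood markers, interferon response, ribosomal protein genes and mitochondrially encoded genes. The ribosomal list was made by a name pattern and also holds the kinase gene rps6kal. Each list with more than 1 measured gene was tested against the other genes with limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. That estimate uses the residuals of the fit, so over 3 stages it takes in stage differences of a genotype effect that list members share. The calls of each list were also counted with p-values adjusted over the list alone. A zygotic set held genes below 1 FPKM at 3 hpf and at 5 FPKM or more at 4.5 hpf in wildtype. A maternal set held genes at 10 FPKM or more at 3 hpf that fell by at least 1 on the log2 scale to 4.5 hpf. To keep the choice of genes apart from the measurement, the sets used for one control set were chosen in the wildtype libraries of the other. Set medians per library were placed among 10000 random lists of the same size matched on mean expression. Progress was the change of the mean log2 level of a set since the matched wildtype at 3 hpf, as a percentage of the wildtype change from 3 to 4.5 hpf.

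Genes named in the text were chosen by a fixed rule. It took nup133 and ahctf1 everywhere. In each wildtype and 3-stage comparison it took the 10 largest rises and falls past the threshold among genes with a mean of at least 5 FPKM that moved the same way in every matched pair. At each single stage it took the 3 largest in each direction, and from each list the members with the largest change among those with a mean of at least 5 FPKM. Genes with clone-type names and symbols shared by several identifiers were passed over. Other named genes are members of the fixed lists or were chosen after their values were seen, as stated there.

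The alternatives were a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio scaling over 9251 genes, rescaling every library to the same sum, no variance trend, no control set term, the own control set only, stricter or same-set definitions of the zygotic and maternal sets, and leaving out each wildtype library or stage in turn. The fits were tested on simulated data in which 100 genes of 13493 were changed by a log2 difference of 1 and another 100 by 2. For MZnup133 over 3 stages, 29% and 88% of these were recovered with 6 false calls, for Tgnup133 33% and 87% with 3, and for Melys 28% and 79% with 4. For MZnup133 at 4.5 hpf the shares were 19% and 53% with 4 false calls, and for wildtype from 3 to 4.5 hpf 34% and 74% with 12. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.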

Results

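Messenger RNA was measured in whole zebrafish embryos around zygotic genome activation, the switch from RNA supplied by the mother to RNA transcribed by the embryo. The series asks how depletion or overexpression of nuclear pore proteins affects this switch. The 15 libraries covered 3, 4 and 4.5 hpf, with 2 wildtype libraries per stage and 1 library per stage for each of MZnup133, Tgnup133 and Melys. No mutant or transgenic group had a replicate at a stage, so the comparisons at single stages rest on 1 library per genotype. Read depth is unknown because only FPKM were used. Mitochondrially encoded transcripts made up 7.29% to 10.23% of the FPKM sum in the wildtype libraries of the nup133 set and 7.37% to 8.65% in those of the elys set. The share was 7.39% to 8.79% in Tgnup133, 5.1% to 6.53% in MZnup133 and 4.76% to 5.31% in Melys.

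The targeted genes were read first, since they check the labels. The transcript of nup133 (ENSDARG00000010078), a scaffold protein of the nuclear pore, was nearly absent in MZnup133, at 0.431, 0 and 0.208 FPKM at 3, 4 and 4.5 hpf. The matched wildtype libraries had 12.6, 13.1 and 11.7 FPKM, and the Tgnup133 libraries had 17.98, 18.4 and 16.4 FPKM. Over 3 stages nup133 fell by 3.49 ± 0.21 (log2, SE) in MZnup133, with a limma adjusted p of 1.3e-05. In Tgnup133 the difference was 0.46 ± 0.21 with an adjusted p of 0.34, higher at 3 of 3 stages but not past the threshold. The transcript of ahctf1 (ENSDARG00000077530), which encodes Elys, a protein that starts pore assembly on chromatin, was at 13.5, 25.8 and 24.1 FPKM in Melys and at 18.7, 26.8 and 19.5 FPKM in its wildtype. Its fitted difference in Melys was -0.07 ± 0.18 with an adjusted p of 0.846, and without the 3 hpf libraries it was 0.121. The level of ahctf1 RNA therefore does not check the Melys label, and a mutation that leaves the transcript in place cannot be seen in these values.

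**Figure D1:**
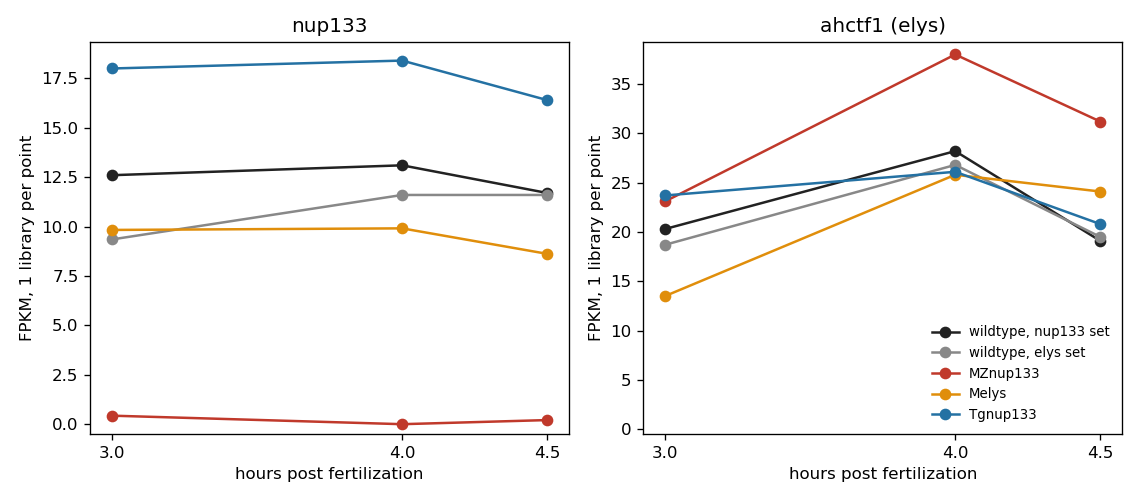
FPKM of nup133 and ahctf1 in each of the 15 libraries, by stage in hpf, with 1 point per library and a line per series. The nup133 values of MZnup133 lie between 0 and 0.431 FPKM, below all other libraries. The ahctf1 value of Melys is the lowest at 3 hpf and lies above both wildtype values at 4.5 hpf.

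In wildtype, early zygotic RNA rose and maternal oocyte RNA fell from 3 to 4.5 hpf. The values are levels of poly(A) RNA, so transcription, RNA loss and changes of poly(A) tails were not measured apart. Of 53 measured early zygotic genes, 49 rose and 2 fell (49 and 2 when adjusted over the list alone), with a median log2 difference of 3.64. Medians that include genes listed at 0 depend on the pseudocount, and with 0.1 this one was 5.63. The orphan gene nnr rose by 8.15 ± 0.14 with an adjusted p of 0.000403, sox3, a transcription factor of early neural fate, by 4.06 ± 0.14 with 0.000988, and noto, a notochord regulator, by 5.36 ± 0.16 with 0.000722. The T-box gene tbx16 was listed at 0 in both 3 hpf libraries and had 199 and 153 FPKM at 4.5 hpf. The members that fell were otx1, by 2.29, and il17rd, by 1.08, both present at 3 hpf, and her7 (-0.48) and wnt8a (0.20) did not pass the threshold. Of 35 maternal oocyte genes, 21 fell and 3 rose (23 and 3 when adjusted over the list alone), with a median of -1.10. The germ plasm organizer buc fell by 3.79 ± 0.22 with an adjusted p of 0.00209, and btg4, which promotes clearance of maternal RNA, changed by -2.67 ± 0.16 with 0.0022.

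Tissue genes followed the zygotic genes. In the mesoderm and endoderm list 20 of 22 members rose and 1, the maternal regulator eomesa, fell, in the dorsal organizer list 12 of 14 rose, in the ventral and BMP list 15 of 21 rose and 3 fell, and in the enveloping layer list 11 of 15 rose and 1, the adhesion gene cdh1, fell. Adjusted over the list alone, these counts were 20 and 1, 12 and 0, 15 and 4, and 11 and 3. These lists are not independent, since 15, 9, 10 and 4 of their members are also early zygotic genes. Of 8 yolk syncytial layer genes 7 rose, and of 13 neuroectoderm genes 8 rose and 1 fell (7 and 0, and 9 and 1, when adjusted over the list alone). Of 77 genes in the ribosomal protein list 66 rose and 1 fell (68 and 1 when adjusted over the list alone), and the one that fell, rps6kal, encodes a kinase. Of 16 germ plasm genes 9 fell and none rose (9 and 1 when adjusted over the list alone). Camera gave adjusted p-values of 7.03e-25 for early zygotic genes, 0.000623 for maternal oocyte genes, 2.44e-13 for mesoderm and endoderm, 1.8e-07 for the dorsal organizer, 5.09e-07 for ventral and BMP genes, 1.03e-05 for the enveloping layer, 3.61e-06 for the yolk syncytial layer, 6.5e-06 for neuroectoderm, 5.05e-22 for ribosomal genes and 0.0268 for germ plasm. With an estimated correlation these adjusted p-values were 0.129, 0.279, 0.129, 0.147, 0.129, 0.205, 0.205, 0.205, 0.129 and 0.319, so none of these calls held.

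Across all genes, 4986 of 13493 differed between 3 and 4.5 hpf, 1909 higher and 3077 lower. From 3 to 4 hpf 937 differed, 487 higher and 450 lower. The gene nnr rose by 7.31 ± 0.14 and the lipid carrier gene apoeb by 6.07 ± 0.25 by 4 hpf, and the germ granule gene tdrd6 fell by 2.80 ± 0.17. From 4 to 4.5 hpf 674 differed, 238 higher and 436 lower. Here the endoderm and yolk layer regulator gata6 rose by 4.06 ± 0.26, the keratin gene krt5 by 3.32 ± 0.23, and the maternal transcription factor sox19b fell by 2.21 ± 0.26. With median-ratio scaling the splits were 2911 higher and 2415 lower for 3 to 4.5 hpf and 357 higher and 243 lower for 4 to 4.5 hpf. That scaling moved the median of all genes from -0.157 to 0.046 and from -0.149 to 0.018, and rescaling every library to the same sum left 0 calls from 4 to 4.5 hpf. Leaving out the wildtype library of the nup133 set at 3 hpf gave 1304 genes for 3 to 4.5 hpf and 95 for 3 to 4 hpf, and leaving out that of the elys set gave 2391 and 112. Without the 4 hpf library of either set 0 genes passed from 3 to 4 hpf or from 4 to 4.5 hpf. Without the 4.5 hpf library of the nup133 set or of the elys set 1621 or 3116 passed for 3 to 4.5 hpf and 0 for 4 to 4.5 hpf.

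MZnup133 embryos had lower levels of early zygotic RNA than wildtype and higher levels of some maternal RNA. Over 3 stages 12 of 53 early zygotic genes fell and 2 rose (22 and 2 when adjusted over the list alone), with a median of -1.21 and 48 of 53 negative. The notochord regulator noto fell by 2.44 ± 0.33 (limma adjusted p 0.00124), sox3 by 1.51 ± 0.25 (0.00353), nnr by 2.54 ± 0.65 (0.0228) and mxtx2, a regulator of the yolk syncytial layer, by 1.63 ± 0.27 (0.00379). At 4.5 hpf nnr stood at 101 FPKM against 530 in wildtype and noto at 21.95 against 146. The members that rose did not behave as zygotic genes in wildtype. The gene otx1 (1.39 ± 0.38) was present at 3 hpf and fell, and her7 (1.78 ± 0.28) had a mean of 1.44 FPKM. Of 35 maternal oocyte genes 10 rose and 2 fell (11 and 3 when adjusted over the list alone), with a median of 0.38. Of the 10, 5 also fell in wildtype from 3 to 4.5 hpf (gdf9, tdrd7a, dazl, slbp2 and grip2a), among them the histone mRNA binding gene slbp2 (1.32 ± 0.31 in MZnup133) and the oocyte growth factor gene gdf9 (1.13 ± 0.29). The other 5 (figla, wee2, zar1, rnf41 and cyp11a1) did not pass in wildtype, so their higher level cannot be read as a slower loss. The oocyte transcription factor gene figla was already at 22.96 FPKM against 3.96 FPKM at 3 hpf. Of the 5 that fell in wildtype, dazl, grip2a, slbp2 and tdrd7a were also higher at 3 hpf. They had 45.4, 37.4, 142 and 92.7 FPKM against 32.5, 17.4, 85.3 and 66.5 FPKM. The other wildtype library at 3 hpf, of the elys set, had 61.15 FPKM of dazl and 156 FPKM of slbp2, more than MZnup133. For dazl and slbp2 the gap at 3 hpf thus lay within the distance between the wildtype libraries. That library had 17.6 FPKM of grip2a and 69.1 FPKM of tdrd7a, near the matched wildtype. For grip2a and tdrd7a, not all of the difference can be a slower loss after 3 hpf, as far as 1 MZnup133 library shows.

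The camera adjusted p was 2e-09 for early zygotic genes and 0.0858 for maternal oocyte genes, and with an estimated correlation the adjusted p-values were 0.212 and 0.591. The difference was larger at 4 and 4.5 hpf than at 3 hpf. Members such as tbx16, chrd and mxtx1 were listed at 0 in the matched wildtype at 3 hpf, so a fall at that stage could not be seen for them. Early zygotic genes that fell numbered 5 at 3 hpf, 23 at 4 hpf and 29 at 4.5 hpf, and 1, 0 and 3 rose. Adjusted over the list alone, 8, 36 and 34 fell and 1, 1 and 5 rose. The medians were -0.23, -1.57 and -1.62 and the means -0.37, -1.72 and -1.33, with camera adjusted p-values of 0.027, 5.91e-15 and 9.71e-12, and adjusted p = 0.898, 0.202 and 0.187 with an estimated correlation. In the planned fit without the 3 hpf libraries, applied to this list after seeing the data, 31 of the 53 fell and 4 rose over the remaining stages. Without the 4 hpf libraries 1 fell and 0 rose, and without the 4.5 hpf libraries 4 fell and 1 rose.

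The broader sets also differed at 4 and 4.5 hpf, with medians near 0 at 3 hpf. At 4 hpf the zygotic set of 458 genes, chosen in the wildtype libraries of the elys set, had a median log2 difference of -1.64 in MZnup133, with 87.1% of genes lower, and at 4.5 hpf of -1.51, with 85.6% lower. The maternal set of 1544 genes had medians of 0.74 and 1.19, with 86.5% and 91.7% higher. At 3 hpf the medians were 0 and 0.03. The genes of the zygotic set were chosen below 1 FPKM at 3 hpf in wildtype, so its median at that stage could hardly show a fall. By 4.5 hpf MZnup133 had covered 55.6% of the wildtype change of the zygotic set and 39.2% of that of the maternal set, and at 4 hpf 19.4% and 11.2%, against 65.3% and 48.1% in the matched wildtype at 4 hpf. These set medians have no replicate check. For scale, the wildtype libraries of the elys set differed from those of the nup133 set at 4.5 hpf by -0.06 for the same zygotic set and 0.36 for the same maternal set. With sets chosen in the nup133 set these gaps were -0.34 and 0.45, so the scale depends on the choice of genes. All of the MZnup133 medians at 4 and 4.5 hpf lay beyond every one of 10000 random lists, but so did the maternal medians between the wildtype sets at these stages and the zygotic ones at 4.5 hpf.

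**Figure D2:**
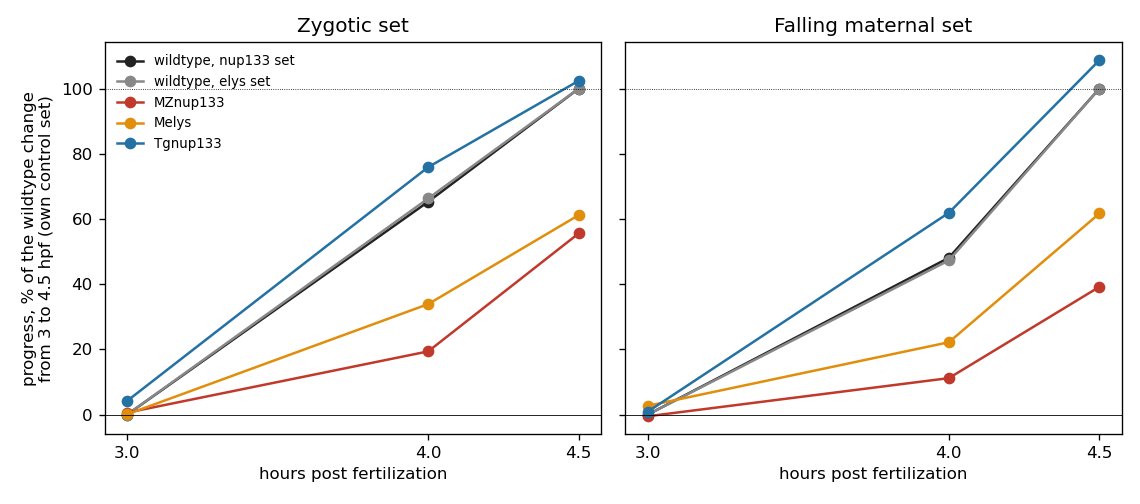
Progress of the zygotic set (left) and the maternal set (right) in percent of the wildtype change from 3 to 4.5 hpf, against stage in hpf, with 1 point per library and a line per series. At 4.5 hpf MZnup133 stands at 55.6% and 39.2% and Melys at 61.2% and 61.7%, while Tgnup133 stands at 102.4% and 108.7%.

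Among tissue lists in MZnup133, the enveloping layer list held 5 members that fell of 15 and none that rose (5 and 0 when adjusted over the list alone), among them the keratin genes krt18a.1 (-2.38 ± 0.71) and krt8 (-2.21 ± 0.56) and the adhesion gene epcam (-0.91 ± 0.07). In the mesoderm and endoderm list 3 of 22 fell and 0 rose (3 and 0 when adjusted over the list alone), which were noto and the Nodal inhibitor genes lft1 (-1.35) and lft2 (-1.27). In the dorsal organizer list noto and the BMP inhibitor gene nog1 (-1.81) fell, 2 of 14 with 0 higher (2 and 0 when adjusted over the list alone). In the ventral and BMP list vox, gata2a and tfap2c fell and id3, a BMP target, rose by 2.24 ± 0.32 (3 and 1 of 21, or 6 and 1 when adjusted over the list alone). In the yolk syncytial layer list mxtx2 alone fell of 8 (3 when adjusted over the list alone), and in neuroectoderm sox3 fell while otx1 and sox19a rose (1 and 2 of 13, also when adjusted over the list alone). The medians were -1.17, -1.23, -1.11, -1.20, -1.45 and -0.94. Camera gave adjusted p-values of 0.000501, 9.99e-06, 0.00128, 0.0037, 0.00268 and 0.0858, which with an estimated correlation became adjusted p = 0.212, 0.212, 0.215, 0.212, 0.212 and 0.323.

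Housekeeping and stress groups also moved in MZnup133, although many of their members, most ribosomal protein genes among them, also rose in wildtype over these stages. Of 77 ribosomal protein genes 29 fell and 1 rose (35 and 1 when adjusted over the list alone), with a median of -0.37. The gene rpl19 fell by 0.97 ± 0.16, whereas rpl10 rose by 2.60 ± 0.23. Of 13 mitochondrially encoded genes 11 fell and 0 rose (12 and 0 when adjusted over the list alone), all 13 were negative, and mt-nd4, a subunit of respiratory complex I, fell by 1.15 ± 0.16. In the heat shock and immediate early list 5 of 13 fell and 0 rose (6 and 1 when adjusted over the list alone), with hspb1, a small heat shock protein gene, at -2.76 ± 0.65 and jun, a transcription factor gene, at -1.94 ± 0.40. The 5 that fell (hspb1, jun, ier2a, hspa8 and dnajb1b) all rose in wildtype from 3 to 4.5 hpf, hspb1 by 5.92 and jun by 3.22. Their lower level can therefore not be told apart from that of the zygotic genes. Camera adjusted p-values were 5.06e-12, 4.08e-08 and 0.00902, each of which became adjusted p = 0.212 with an estimated correlation. Without the 4 hpf libraries 1 ribosomal and 0 mitochondrial genes fell, and without the 4.5 hpf libraries 2 and 0 fell. Without the 3 hpf libraries 48 ribosomal and 13 mitochondrial genes fell.

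Across all genes, 2968 differed over 3 stages in MZnup133, 1846 higher and 1122 lower. With median-ratio scaling, which moved the median of all genes from 0.147 to 0.000, the split was 1421 higher and 1570 lower. At 3, 4 and 4.5 hpf 405, 1330 and 2898 genes differed, with 160, 628 and 1819 higher and 245, 702 and 1079 lower. With median-ratio scaling 467 were higher and 843 lower at 4 hpf and 1136 higher and 1631 lower at 4.5 hpf, where the median of all genes moved from 0.262 to 0.015. Without the 4 hpf libraries 232 genes passed over the remaining stages, and without the 4.5 hpf libraries 771.

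The largest single differences in MZnup133 were near all-or-none. The vesicle fusion gene vamp8 had 31.6, 33.1 and 24.4 FPKM in MZnup133 and was listed at 0 in all wildtype libraries. The reverse held for the nuclear export receptor gene xpo6, listed at 0 at all stages in MZnup133 against 152, 111 and 34.8 FPKM in wildtype (adjusted p 1.84e-05), and for the condensin gene ncapg, listed at 0 against 52.97, 67.9 and 61.6 FPKM (2.9e-06). The genes gtf3ab, mettl2a and eif4ebp1 were also listed at 0 in the 3 MZnup133 libraries, against 53.6, 42.5 and 29.0, 43.4, 39.6 and 43.0, and 20.0, 35.5 and 49.8 FPKM in wildtype. A value of exactly 0 can be an estimate that failed. At single stages the gene camta1 was listed at 0 in 14 libraries and at 435 FPKM in MZnup133 at 4.5 hpf, and sox19a, a relative of the maternal regulator sox19b, had 56.6 FPKM there against 0.423 FPKM in wildtype.

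Melys embryos also had lower zygotic RNA at 4 and 4.5 hpf, with few single genes past the threshold over 3 stages. The medians were smaller in size than in MZnup133, but whether the lines differ in them was not tested. Of 53 early zygotic genes 2 fell and 3 rose (2 and 3 when adjusted over the list alone), with a median of -0.71 and 44 of 53 negative. The genes that fell were noto (-1.91 ± 0.33, limma adjusted p 0.00662) and sox3 (adjusted p 0.034), which stood at 58.1 and 55.9 FPKM at 4 and 4.5 hpf against 107 and 98.5 FPKM. Those that rose were isg15, an interferon-stimulated gene (adjusted p 0.0228, 163 and 337 FPKM at 4 and 4.5 hpf against 74.7 and 115 FPKM), the apelin receptor gene aplnrb (1.54 ± 0.39) and her7 (1.58 ± 0.28). At 4.5 hpf nnr stood at 58.3 FPKM against 466 in wildtype and noto at 48.0 against 114. By stage, 2, 7 and 8 early zygotic genes fell and 0, 0 and 2 rose at 3, 4 and 4.5 hpf, or 4, 16 and 23 and 0, 2 and 4 when adjusted over the list alone. The stage medians were -0.10, -0.75 and -1.01.

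Camera gave an adjusted p of 0.00214 for early zygotic genes over 3 stages (adjusted p = 0.419 with an estimated correlation). At 3, 4 and 4.5 hpf it gave 0.64, 2.5e-06 and 2.63e-09, and the last 2 became adjusted p = 0.38 and 0.26 with an estimated correlation. In the planned fit without the 3 hpf libraries, again applied to this list after seeing the data, 14 of the 53 fell and 1 rose, while without the 4 hpf or the 4.5 hpf libraries 0 passed. The zygotic set of 519 genes, chosen in the wildtype libraries of the nup133 set, had medians of 0, -0.91 and -1.31 at 3, 4 and 4.5 hpf, with 77.5% lower at 4 hpf and 81.9% at 4.5 hpf. As in MZnup133, the choice of genes left little room for a fall at 3 hpf. The maternal set of 2142 genes had medians of 0.01, 0.35 and 0.53. Between the wildtype sets these sets differed by -0.34 and 0.45 at 4.5 hpf, but they were chosen in 1 of the wildtype series compared, which can shift the gap. Sets chosen in the other series gave -0.06 and 0.36. With either choice the gap between wildtype libraries was not small beside the maternal median of Melys at that stage. By 4.5 hpf Melys had covered 61.2% of the wildtype change of the zygotic set and 61.7% of that of the maternal set, and at 4 hpf 33.9% and 22.2% against 66.3% and 47.3% in its wildtype.

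**Figure D3:**
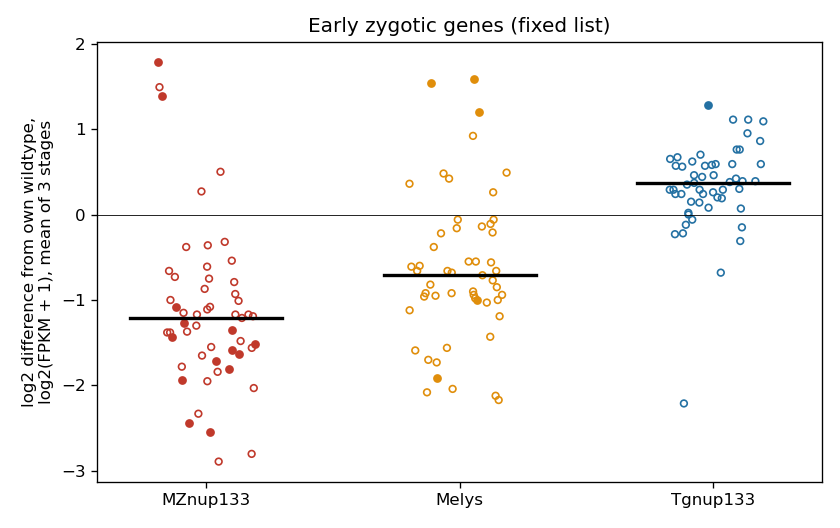
Log2 difference from the matched wildtype, fitted over 3 stages, for the 53 measured early zygotic genes. Each point is a gene, filled where it passed the adjusted p threshold, and the bar is the median. In MZnup133 48 of 53 genes lie below 0, in Melys 44, and in Tgnup133 45 lie above 0.

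Other groups in Melys differed in part from those in MZnup133. Of 17 genes in the damage response list 3 rose and 1 fell (5 and 1 when adjusted over the list alone), with a median of 0.64. The apoptosis gene bbc3 rose by 2.42 ± 0.64 (adjusted p 0.042), reaching 30.2 and 47.6 FPKM at 4 and 4.5 hpf against 2.85 and 2.03 FPKM, the growth arrest gene gadd45aa rose by 1.72 ± 0.46 (0.0453), and rps27l rose by 1.02 ± 0.25. The kinase gene plk3 fell by 1.24 ± 0.23. Camera did not call the list, with an adjusted p of 0.144. Of 13 mitochondrially encoded genes 6 fell and 0 rose (10 and 0 when adjusted over the list alone), with all 13 negative and mt-cyb, which encodes cytochrome b, at -1.08 ± 0.17. The camera adjusted p was 4.75e-08, and adjusted p = 0.419 with an estimated correlation. Without the 4 hpf or the 4.5 hpf libraries 0 mitochondrial genes passed, and without the 3 hpf libraries 10 fell. Of 77 ribosomal protein genes 9 rose and 5 fell (9 and 5 when adjusted over the list alone), or 3 and 5 with median-ratio scaling. Of 35 maternal oocyte genes 6 rose and 3 fell (9 and 4 when adjusted over the list alone), with grip2a, a germ plasm component, up by 1.37 ± 0.21. Camera adjusted p-values for these 2 lists were 0.232 and 0.12.

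Across all genes 1368 differed over 3 stages in Melys, 740 higher and 628 lower, or 620 higher and 796 lower with median-ratio scaling. At 3, 4 and 4.5 hpf 155, 229 and 401 genes differed, with 55, 75 and 183 higher and 100, 154 and 218 lower. At 4.5 hpf median-ratio scaling moved the median of all genes from 0.181 to 0.000 and gave 167 higher and 354 lower. Without the 4 hpf libraries 147 genes passed over the remaining stages, and without the 4.5 hpf libraries 368. The gene ctsd, for the lysosomal protease cathepsin D, was at 0, 1.23 and 0 FPKM in Melys against 103, 91.6 and 72.1 FPKM in its wildtype (adjusted p 7.29e-07), and the DNA repair gene fancg was listed at 0 at all stages against 30.3, 22.2 and 14.5 FPKM. The nuclear receptor gene nr4a1 rose by 4.31 ± 0.34 (0.000107), from at most 1.54 FPKM in its wildtype to 33.1, 34.3 and 26.1 FPKM. The gene ppp1r8b was at 90.1, 102 and 101 FPKM against 0.0668, 0.107 and 1.91 FPKM, although the wildtype libraries of the nup133 set had 18.5, 21.7 and 38.6 FPKM, so that this difference also separates the wildtype sets.

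Tgnup133 embryos resembled wildtype most, and their early zygotic genes leaned higher. Of 53 early zygotic genes 1 rose and 0 fell (1 and 0 when adjusted over the list alone), which was klf2a, a Kruppel-like transcription factor gene (1.28 ± 0.26, limma adjusted p 0.039). The median was 0.36 and 45 of 53 were positive. Camera gave an adjusted p of 0.0048 (adjusted p = 0.88 with an estimated correlation). The mesoderm gene tbxta was at 20.8 and 84.0 FPKM at 4 and 4.5 hpf against 8.76 and 39.8 FPKM in wildtype, and the BMP inhibitor gene chrd at 17.6 and 61.2 against 2.81 and 30.1 FPKM, but neither passed the threshold (adjusted p 0.148 and 0.504). The zygotic set had medians of 0, 0.47 and 0.14 at 3, 4 and 4.5 hpf and the maternal set of -0.01, -0.24 and -0.15. At 4 hpf 75.9% of the wildtype change of the zygotic set and 61.9% of that of the maternal set had been covered, against 65.3% and 48.1% in wildtype. The distance at 4 hpf in the maternal set, -0.24, is near the 0.20 between the wildtype sets for the same genes.

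Over 3 stages 263 genes differed in Tgnup133, 108 higher and 155 lower. Without the 3, 4 or 4.5 hpf libraries 90, 1 or 18 genes passed. The small GTPase gene kras rose (adjusted p 0.00604), at 59.7, 92.3 and 99.2 FPKM against 3.14, 6.04 and 10.4 FPKM, and the separase gene espl1, needed to part sister chromatids, by 2.03 ± 0.17 (0.000703). The surface glycoprotein gene thy1 fell by 4.18 ± 0.15 (2.76e-06) and the endosomal GTPase gene rab5b fell (0.00125), at 2.19, 0.466 and 5.18 FPKM against 30.4, 36.7 and 40.8 FPKM. The RNA-binding gene tia1l was at 5.87, 0.284 and 1.56 FPKM against 89.5, 130 and 160 FPKM. Of these, thy1 was also low in MZnup133 (37.9, 25.5 and 18.2 FPKM). In Melys thy1 was at 104, 87.5 and 83.3 FPKM against 354, 256 and 179 FPKM. There espl1 was raised too, at 46.5, 35.6 and 33.1 against 11.3, 13.6 and 10.8 FPKM. Melys also had low tia1l, at 0, 19.3 and 0.674 against 111, 122 and 143 FPKM. In MZnup133 espl1 was near wildtype and tia1l higher. So thy1, espl1 and tia1l were not particular to Tgnup133, whereas kras and rab5b did not move alike in Melys. At single stages 2, 6 and 4 genes differed at 3, 4 and 4.5 hpf, of which 0, 2 and 1 were higher and 2, 4 and 3 lower, and rescaling every library to the same sum left 0 higher and 3 lower at 4.5 hpf. Of 36 cell cycle genes 1 fell and 0 rose (1 and 4 when adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.00729 (adjusted p = 0.169 with an estimated correlation). The member that fell was 1 of 2 identifiers that carry the symbol rrm2, so its identity is uncertain. No ribosomal protein gene passed in limma (also when adjusted over the list alone), although 60 of 77 were positive with a median of 0.18, and camera gave an adjusted p of 8.79e-06 (adjusted p = 0.88 with an estimated correlation).

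The change from 3 to 4.5 hpf was compared with the wildtype change to ask whether the genotypes altered the course itself. For Tgnup133 and Melys limma called 0 genes, with 1009 and 2282 at an unadjusted p under 0.05. For MZnup133 12 genes passed, 4 higher and 8 lower, with 3120 at an unadjusted p under 0.05. Median-ratio scaling moved the median of all genes in these comparisons from -0.119 to 0.03, from 0.215 to 0.02 and from 0.197 to 0.01. As a group, early zygotic genes changed less in MZnup133, with a median of -1.15 (camera adjusted p 1.21e-07, and adjusted p = 0.232 with an estimated correlation), and in Melys, with -1.12 (6.36e-07, and adjusted p = 0.268 with an estimated correlation). No early zygotic gene passed in either over all genes, and 21 and 16 were lower and 5 and 4 higher when adjusted over the list alone.

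MZnup133 and Melys used separate control libraries, so their differences from wildtype can be set side by side. Across 13493 genes, which are not independent replicates, the fitted differences correlated with Pearson's r of 0.377 and Spearman's rho of 0.409. Of the called genes 337 were higher in both, where 101 would be expected for independent lists, and 244 were lower in both, where 52.2 would be expected. A further 59 were higher in MZnup133 and lower in Melys (85.9 expected) and 40 the reverse (61.5 expected). A test of the difference between the genotypes, added after seeing the data, called 711 genes, 372 higher in MZnup133 and 339 lower. Without the 3, 4 or 4.5 hpf libraries that count was 457, 46 or 202. For MZnup133 and Tgnup133, which share their controls, r was 0.235 and the covariance 0.111, where unchanged groups simulated against those controls gave 0.502 and 0.0801. The shared wildtype libraries could not be split, since each part would hold fewer than 2 libraries per stage, so part of the overlap (74 higher in both where 14.8 were expected, 61 lower in both where 12.9 were expected) may come from the controls. With Tgnup133 measured against the wildtype libraries of the elys set, a control chosen after seeing the data, r was 0.019. For Tgnup133 and Melys, which have separate controls, r was 0.042. Even so, 39 genes were higher in both (5.92 expected) and 48 lower in both (7.21 expected). A further 25 were higher in Tgnup133 and lower in Melys (5.03 expected) and 18 the reverse (8.5 expected). An excess over independent lists was therefore not particular to MZnup133 and Melys. The lists came from 1 fit with a common variance estimate per gene, so genes with a small spread can pass in several of them without a shared effect. The expected numbers are for that reason no more than a rough scale. The wildtype series of the elys set differed from that of the nup133 set in 104 genes, 40 higher and 64 lower, in a separate fit of all 15 libraries. Stage differences of the mutant and transgenic effects enter the residual spread of that fit, so this count is not on the same scale as those of the genotypes.

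**Figure D4:**
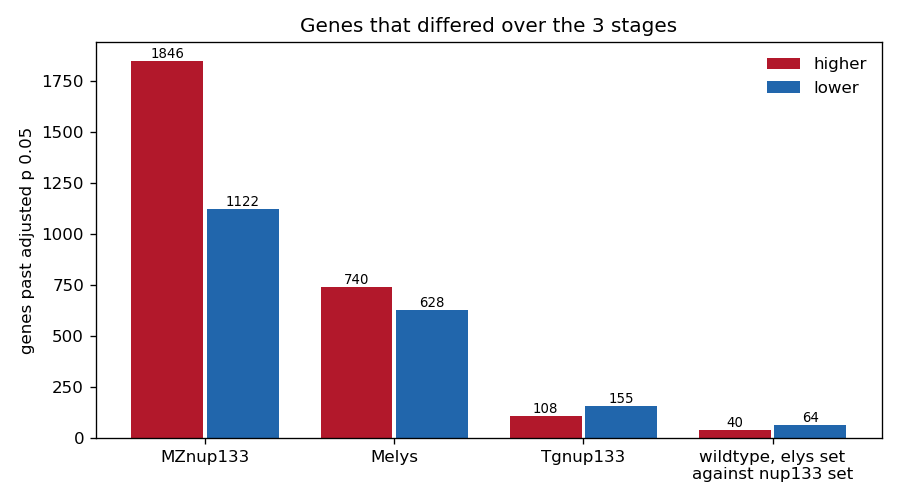
Number of genes past the adjusted p threshold, higher and lower, for each comparison over 3 stages. MZnup133 had 2968 genes over 3 stages, Melys 1368, Tgnup133 263 and wildtype against wildtype, from a separate fit, 104.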

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

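The 2 tests of a delay along the wildtype course, the test of a background shared between the mutant lines and the test of MZnup133 against Melys were chosen only after the results were seen.

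The change from 3 to 4.5 hpf differed from the wildtype change in 12 genes in MZnup133, 4 higher and 8 lower, which is a difference between groups by a test of the interaction. Of these, 5 had no spread between the paired wildtype libraries, where the test rests on the prior variance. The gene spata6l was at 46.8, 0 and 0 FPKM at 3, 4 and 4.5 hpf in MZnup133 against 29.8, 44.0 and 49.0 FPKM in wildtype. The effects of MZnup133 and Melys over 3 stages differed from each other in 711 genes, 372 higher and 339 lower in MZnup133.

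The zygotic sets were lower in MZnup133 and Melys. Scaling between libraries is argued against, since with median-ratio scaling the median in MZnup133 at 4.5 hpf was -1.792, while the largest wildtype-to-wildtype median was 0.437. A uniform delay could not be decided from the gap between zygotic and maternal progress, which was 16.4 percentage points in MZnup133 at 4.5 hpf, since wildtype at 4 hpf had a gap of 17.2. Along the wildtype course, the maternal progress of MZnup133 at 4.5 hpf lay -1.8 points from the value expected at its zygotic progress, and that of Melys 18 points. The other wildtype series, with sets chosen in its own libraries, lay -12.7 points off at 4 hpf and -18.1 at 4.5 hpf. The latter rests on a zygotic progress of 104.6%, beyond the end of the course, where the expected value was held at 100. A delay stays open in MZnup133. For Melys, which lay further off than the value at 4 hpf and in the other direction, this test cannot decide. A loss of transcription specific to zygotic genes through the pore protein, a difference in staging and a difference between clutches stay open as well and were not tested.

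In MZnup133 62 genes were on or off at all 3 stages (25 on, 37 off, nup133 among the latter), in Melys 38, in Tgnup133 5 and between the wildtype series 4. These 4 (paqr3a, prkcq, cfdp1 and zgc:56699) were all among the 38 of Melys, which had the state of the wildtype of the nup133 set. Their state in Melys therefore also occurs without loss of the pore protein. The gene ppp1r8b, off in MZnup133, was at 0.0668, 0.107 and 1.91 FPKM in the wildtype of the elys set. FPKM estimates that fail at random between libraries are argued against, since regroupings that mixed the genotypes gave at most 2 such genes beside the 62, but estimates that fail because a line carries other alleles or gene copies are not excluded. A haplotype linked to nup133 could not be decided. Of the 50 nearest genes 0 were on or off, but the median of 10000 random windows was also 0, and only 77.4% of the genes could be placed. A background shared between the mutant lines fits, since 5 genes were on or off in both in the same direction (vamp8 and mettl2a among them) where 0.11 would be expected, but this sharing was not particular to the mutants. Tgnup133 shared 2 of its 4 on genes with Melys (0.008 expected) and 1 with MZnup133 (0.01 expected), and cfdp1 was on in MZnup133 and off in Melys. For genes that did not also vary between the wildtype series, loss of the pore protein itself stays open and was not tested.

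The counts over 3 stages were set beside all 10 splits of each 6 libraries into 3 and 3, too few for a share under 0.05, so a chance arrangement of the libraries cannot be excluded by this alone. In each comparison 1 split, the real one, gave as many genes. The real and the highest other counts were 2968 and 1 in MZnup133, 263 and 1 in Tgnup133, 1368 and 6 in Melys and 104 and 1 between the wildtype series. The last count compares no mutant, so differences between separately raised or processed sets may make up part of any of these counts. That count comes from a separate fit, whose residual spread takes in the mutant and transgenic libraries. At single stages 1058 to 1283 genes differed by at least 1 in log2(FPKM + 1) between the wildtype libraries beside 1383 to 1614 in Tgnup133.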

How the results depend on the processing

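The test of MZnup133 against Melys with its alternatives was chosen only after the result was seen. Direction was checked for 235 calls of named genes and 32 list calls, not for all called genes, and 0 of these changed direction, while the ahctf1 difference in Melys, which did not pass, changed sign without the 3 hpf libraries. The larger side of the split into higher and lower genes did change in some comparisons. With median-ratio scaling it turned in wildtype from 4 to 4.5 and from 3 to 4.5 hpf, in MZnup133 at 4.5 hpf and over 3 stages, in Melys over 3 stages and in MZnup133 against Melys. With no filter it turned in MZnup133 at 3 and 4 hpf and in its change, and in Tgnup133 and Melys at every stage. With a filter at 5 FPKM it turned in wildtype from 3 to 4 hpf, MZnup133 at 4 hpf and in its change, Melys at 4.5 hpf and MZnup133 against Melys. Without a variance trend it turned in Tgnup133 at 3 and 4 hpf and with no control set term at 4 hpf. Over 3 stages it turned in MZnup133 and Melys without the 4 hpf libraries, without the 4.5 hpf libraries in Melys, and in MZnup133 against Melys without any of the stages. Depth is unknown, so what it limits was not measured. The fits over 3 stages compare each library with the wildtype of its own control set and stage, so the match is part of the design. Where genes or libraries were left out, fewer tests or fewer degrees of freedom account for part of a change, and otherwise the cause was not tested. Lone libraries were assumed to vary like the wildtype ones. Of the 235 gene calls 210 held with a pseudocount of 0.1, 174 with no filter, 233 with a filter at a mean of 5 FPKM, 232 with median-ratio scaling, 211 with a common sum and 197 without a variance trend. Of 119 calls over 3 stages 99, 42 and 58 held without the 3, 4 and 4.5 hpf libraries and 94 with the own control set only. Of the wildtype calls, 0 of 40 held without either 4 hpf wildtype library, and of 96 calls 74 and 82 held without the 3 hpf library of the nup133 or elys set and 64 and 73 without that of 4.5 hpf. Of 32 list calls 31 held with median-ratio scaling and 0 with an estimated correlation, where early zygotic genes had adjusted p = 0.129 in wildtype, 0.212 in MZnup133, 0.88 in Tgnup133 and 0.419 in Melys.

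Counts of genes were as follows. For wildtype from 3 to 4 hpf (937), no filter gave 80 and leave-one-out 0 to 112. From 4 to 4.5 hpf (674) a pseudocount of 0.1, no filter, a common sum, no variance trend and leave-one-out (0 to 0) each gave 0 in limma, no control set term 353 and a filter at 5 FPKM 1580. From 3 to 4.5 hpf (4986) no filter gave 2723 and leave-one-out 1304 to 3116. For MZnup133 at 3 hpf (405) a filter at 5 FPKM gave 794 and no variance trend 269, and at 4 and 4.5 hpf (1330, 2898) no filter gave 695 and 1084. For the MZnup133 change (12) a pseudocount of 0.1 gave 5, no filter 648, a filter at 5 FPKM 288, a common sum 7 and no control set term 59. For Tgnup133 at 3 hpf (2) these gave, for the pseudocount 1, no filter 255, filter at 5 FPKM 49 and no control set term 6. At 4 hpf (6) no filter gave 344, the filter at 5 FPKM 38 and no control set term 17, and at 4.5 hpf (4) no filter gave 580, the filter at 5 FPKM 32 and no variance trend 0. The Tgnup133 change (0) had 641 with no filter. For Melys at 3 hpf (155) no filter gave 257, the filter at 5 FPKM 443 and no variance trend 76. At 4 hpf (229) a pseudocount of 0.1 gave 120, no filter 440, the filter at 5 FPKM 571 and no variance trend 129, and at 4.5 hpf (401) these gave 138, 955, 1030 and 191. The Melys change (0) had 679 with no filter, 4 with the filter at 5 FPKM and 2 with no control set term. With no filter, 460 of the 648, 583 of the 641 and 568 of the 679 genes had no spread between paired wildtype libraries, which shows the cause for most of them. Over 3 stages the own control set only gave 1911 for MZnup133 (2968), 132 for Tgnup133 (263) and 731 for Melys (1368), and leave-one-out gave 232 to 4020, 1 to 90 and 147 to 1257. MZnup133 against Melys (711) had 46 to 457. The ahctf1 difference in Melys (-0.068) was -0.249 to 0.121.

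The zygotic median of MZnup133 at 4 hpf (-1.642) was -2.344 with stricter sets, -1.338 with the set chosen in the same controls, -2.789 with a pseudocount of 0.1 and -1.952 with a common sum, and at 4.5 hpf (-1.507) -1.771, -1.827, -1.78 and, with median-ratio scaling, -1.792. The maternal median at 4 hpf (0.741) was 1.164 with stricter sets, and at 4.5 hpf (1.192) 1.589 with stricter sets, 0.915 with median-ratio scaling and 1.367 with a common sum. The zygotic median of Melys at 4 hpf (-0.905) was -1.28 with stricter sets, -1.126 with the same controls and -1.375 with a pseudocount of 0.1, and at 4.5 hpf (-1.308) -1.601, -1.576, -1.546 and, with median-ratio scaling, -1.457.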

Other observations

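No test in this part was chosen after the results were seen, but the single genes of its last paragraph were picked after.

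Nuclear pore and transport genes changed little as groups and moved through single members. In MZnup133 5 of 30 pore genes fell and 2 rose (5 and 3 when adjusted over the list alone). Beside nup133 itself, the central channel gene nup54 (-0.79 ± 0.18) and the cytoplasmic side gene nup88 (-0.70 ± 0.15) fell, and the RNA export gene rae1 rose (0.66 ± 0.17). The list's median was 0.02, its mean -0.11 and the direction of camera down (adjusted p 0.267), and the median was -0.143 with median-ratio scaling. Of 31 transport genes 3 fell and 3 rose (3 and 3 when adjusted over the list alone, camera adjusted p 0.238). The importin gene ipo9 fell by 2.01 ± 0.13, and kpna7, a maternal importin alpha gene, rose by 1.73 ± 0.26 at 278, 204 and 128 FPKM against 126, 54.5 and 27.8 FPKM. The median was 0.03, the mean -0.19, and the median -0.139 with median-ratio scaling. In Melys nup160, which encodes a partner of Nup133 in the same pore subcomplex, rose (0.81 ± 0.15, adjusted p 0.0103), ran, the GTPase that drives nuclear transport, fell (-0.62 ± 0.12, 0.0118), and 2 pore genes rose and 2 fell (camera adjusted p 0.815). In Tgnup133 nup62l was the 1 pore gene that fell (-0.61 ± 0.10).

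Among maternal regulators of genome activation, foxh1, a Nodal effector gene, fell by 1.22 ± 0.17 in MZnup133, at 40.1, 50.3 and 55.2 FPKM against 124, 128 and 93.0 FPKM, and mych fell by 1.02 ± 0.26. In these data mych behaved as a zygotic gene, at 6.13 FPKM at 3 hpf and 251 FPKM at 4.5 hpf in wildtype. Of the 19 genes 3 fell and 2 rose (3 and 3 when adjusted over the list alone, camera adjusted p 0.238), and in wildtype 7 fell and 6 rose (7 and 7, camera adjusted p 0.677), with a median of -0.16, a mean of 0.11 and a direction of up in camera. The maternal RNA of sox19b was at 504 and 224 FPKM at 4 and 4.5 hpf in MZnup133 against 282 and 43.7 FPKM in wildtype, and that of buc at 278 and 130 against 96.3 and 23.8 FPKM, but neither passed the threshold over 3 stages (adjusted p 0.155 and 0.194). In the germ plasm list 3 of 16 rose and 1, the piRNA pathway gene piwil1, fell (-0.95 ± 0.14; 4 and 2 when adjusted over the list alone), with a median of -0.01, a mean of 0.33 and a camera adjusted p of 0.918. Of 6 interferon genes 1 rose in MZnup133, stat2 (1.23 ± 0.30), and 1 in Melys, isg15 (1 and 0, and 3 and 1, when adjusted over the list alone), with camera adjusted p-values of 0.896 and 0.175. Of 36 cell cycle genes 8 fell and 4 rose in MZnup133 (8 and 5 when adjusted over the list alone, camera adjusted p 0.0858), among them the replication origin gene orc1 (-1.68 ± 0.19). The only measured adult blood gene, hbaa2, rose in wildtype by 2.59 ± 0.22.

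The ribosomal protein gene rpl10 was at 199, 210 and 225 FPKM at 3, 4 and 4.5 hpf in MZnup133 and at 225, 178 and 264 FPKM in Melys, against 20.2, 33.7 and 57.0 and 26.2, 34.1 and 41.3 FPKM in wildtype. The gene rrm2, for a subunit of ribonucleotide reductase, is carried by 2 identifiers. In Tgnup133 and Melys 1 identifier was at 1.197 to 7.09 FPKM and the other at 880 to 1320 FPKM, and in the wildtype libraries at 265 to 321 and 423 to 594.5 FPKM. MZnup133 went the other way at 4 and 4.5 hpf but not at 3 hpf, with 370, 776 and 750 FPKM for the former identifier at 3, 4 and 4.5 hpf and 429, 33.9 and 41.8 FPKM for the latter. The gene zgc:56699 was listed at 0 in the wildtype of the elys set, with means of 256 FPKM in that of the nup133 set and 787 FPKM in Melys. The number of genes that differed by at least 1 in log2(FPKM + 1) from the matched wildtype was 2506, 3495 and 4536 in MZnup133, 2137, 2486 and 2677 in Melys, 1383, 1614 and 1556 in Tgnup133 and 1058, 1168 and 1283 between the wildtype libraries, with 1 library on each side. For low genes this asks for more than a 2-fold difference in FPKM.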
